A study of Mus musculus with 24 samples.

How the data were processed

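RNA was measured in the livers of 24 mice of 2 inbred strains, 129S1/SvImJ and C57BL/6J, fed either chow or a high-fat diet, with 1 library per mouse. Per the labels' protocols, total RNA was isolated with QIAzol and a column kit, treated with DNase and depleted of ribosomal RNA, and libraries were prepared with a kit that keeps the strand of the transcript. The submitters' processing notes name Trimmomatic 0.36, Bowtie2 2.2.3, STAR 2.5.4b, DESeq2 1.26.0 and the mm10 genome build, without saying which tool did what. The gene annotation release and the strand setting used for counting are not given in the sources used here. The labels do not give the age of the mice, the composition of the diets or the length of feeding.

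The authors deposited raw gene counts, as 1 file per library and as 1 matrix of all libraries, and the values of all 24 per-library files were identical to the columns of the matrix. The authors also deposited a matrix on a log2-like scale, named as variance-stabilized values, in which a gene with 0 counts reads 4.243. All tests started from the raw counts, and the variance-stabilized values were used for 1 alternative. The matrix holds 53677 gene identifiers, of which 53582 matched the GENCODE M21 annotation of mm10 without the version suffix and 51427 with it. The 95 unmatched identifiers held 0.0075% of the counts. Gene symbols, mm10 coordinates and gene types were taken from that annotation. The mitochondrially encoded genes, the genes of unplaced scaffolds and a part of the mostly non-coding genes of chromosomes 16, 17, 18 and 19 have no identifier in the tables used and are not analysed here.

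Libraries were grouped by the strain and diet in their labels: 5 of 129S1/SvImJ on chow, 6 of 129S1/SvImJ on high-fat diet, 6 of C57BL/6J on chow and 7 of C57BL/6J on high-fat diet. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough counts for the group sizes were kept by filterByExpr, which left 14533, library sizes were scaled by the trimmed mean of M-values, and robust quasi-likelihood models with 1 mean per group were fitted to all 24 libraries. There were 5 comparisons: the effect of diet in each strain, the difference between strains (129S1/SvImJ minus C57BL/6J) on each diet, and the interaction, which is the diet effect in 129S1/SvImJ minus that in C57BL/6J. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested). Every adjusted p of a gene comes from the edgeR quasi-likelihood test, which is two-sided, and fold changes are on the log2 scale with a prior count of 0.125. Levels are CPM, counts scaled to the library size as adjusted by edgeR, with SD over the mice of a group.

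The design, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. There were 39 gene lists (pathways, cell type markers and gene families of liver), of which 37 had tested members and 36 had the 5 or more needed for a set test. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals and with fry. Fry asks whether the genes of a list changed, without setting them against the other genes. Which lists to describe was chosen after the set tests were seen. The rule for naming genes took, in each comparison, up to 6 called genes per direction with the largest fold change, a mean of at least 5 CPM in the higher group and, except in the interaction, no overlap of CPM (pseudocount 0.5) between the groups compared, up to 4 members with the smallest p of each list described, and 9 fixed genes whatever their p. A fold against a group with no counts is a lower bound, computed from a floor of 3 counts over the whole group, and covers counting error only. Genes with near-identical copies are named as uncertain, since the counting could have split their reads.

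Each mouse is 1 library, so the p-values of genes measure the spread between mice. Camera p-values at the preset correlation set the genes of a list against the other genes and do not measure that spread. The mouse identifiers carry numbers, 119 and 120 for 129S1/SvImJ on chow and 109 and 113 on high-fat diet. They were 58 and 61 for C57BL/6J on chow and 1 and 16 on high-fat diet, so no number was shared between groups. No pair of libraries within a group matched within sampling noise (chi-square per degree of freedom of 5.56 to 78.8 over 61 pairs). Total counts ran from 6707013 to 13124881 per library. The procedure was tested on simulated data, drawn with the depth of the 24 libraries and the spread edgeR estimated for each gene. It recovered 49.3% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 90.9% of those changed 4-fold for diet in 129S1/SvImJ (14334 genes). The shares were 68.7%, 79.1% and 97.0% for diet in C57BL/6J (14321 genes). They were 49.3%, 80.6% and 97.0% for strain on chow (14348 genes) and 49.3%, 80.6% and 98.5% for strain on high-fat diet (14327 genes). For the interaction they were 37.3%, 71.6% and 87.9% (14347 genes). Each share rests on 66 or 67 changed genes. Of the 146 to 190 calls per simulation, between 4 and 8 were false. The real comparisons apart from the interaction called far more genes, so these shares do not give the power in the real data.

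The alternatives of that first set were other size factors (RLE, upper-quartile), DESeq2 1.42.0, limma-voom, limma-trend on the variance-stabilized values, no filter, a filter at a mean of 1 CPM, a fit to the compared groups alone, the replicate number as a block, the number in the mouse identifier as a term, a test against a 1.5-fold change (glmTreat), library sizes without the 10 most abundant genes, and each library left out in turn. Further alternatives were chosen after seeing the data. Libraries were split into a low and a high level of the small nuclear RNA 7SK, at the widest gap of log2 CPM within each strain. The highest low and lowest high library read 3218 and 4657 CPM in 129S1/SvImJ, and 2765 and 3493 CPM in C57BL/6J. Such a cut gives 2 levels in any data, so they need not be separate groups of libraries. Each group held 2 to 5 libraries of each level, so every comparison was repeated within the low and within the high level and with the level as a term. The labels name no such batch. Every comparison was also repeated without chow replicate 1 of 129S1/SvImJ and high-fat replicate 5 of C57BL/6J, which held transcripts of adipocyte genes (Adipoq at 0.866 and 1.23 CPM, against at most 0.169 in the other libraries). Some of the single genes that the tests covered are not reported here, while counts of genes include them.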

Results

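RNA abundance was measured by sequencing in the livers of 24 mice, 1 library each, of the inbred strains 129S1/SvImJ and C57BL/6J. The mice had been fed chow or a high-fat diet, and the labels give 5 mice of 129S1/SvImJ on chow, 6 of 129S1/SvImJ on high-fat diet, 6 of C57BL/6J on chow and 7 of C57BL/6J on high-fat diet. Total gene counts per library ran from 7607255 to 9184270 in 129S1/SvImJ on chow and from 6707013 to 13035534 on high-fat diet. In C57BL/6J they ran from 10162138 to 12826048 on chow and from 8294723 to 13124881 on high-fat diet. The livers of 129S1/SvImJ on chow had 19578 ± 456 genes with a count (SD, n = 5) and those of C57BL/6J on chow 20625 ± 259 (SD, n = 6). On high-fat diet the numbers were 20220 ± 874 (SD, n = 6) and 20790 ± 677 (SD, n = 7). On chow every 129S1/SvImJ library held fewer counts than any C57BL/6J library, so depth and strain cannot be told apart for these numbers. Albumin (Alb) held 5.41% of all counts, the desaturase gene Scd1 2.19% and the apolipoprotein gene Apob 2.10%. The first principal component held 45.7% of the variance and the second 12.5%.

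**Figure D1:**
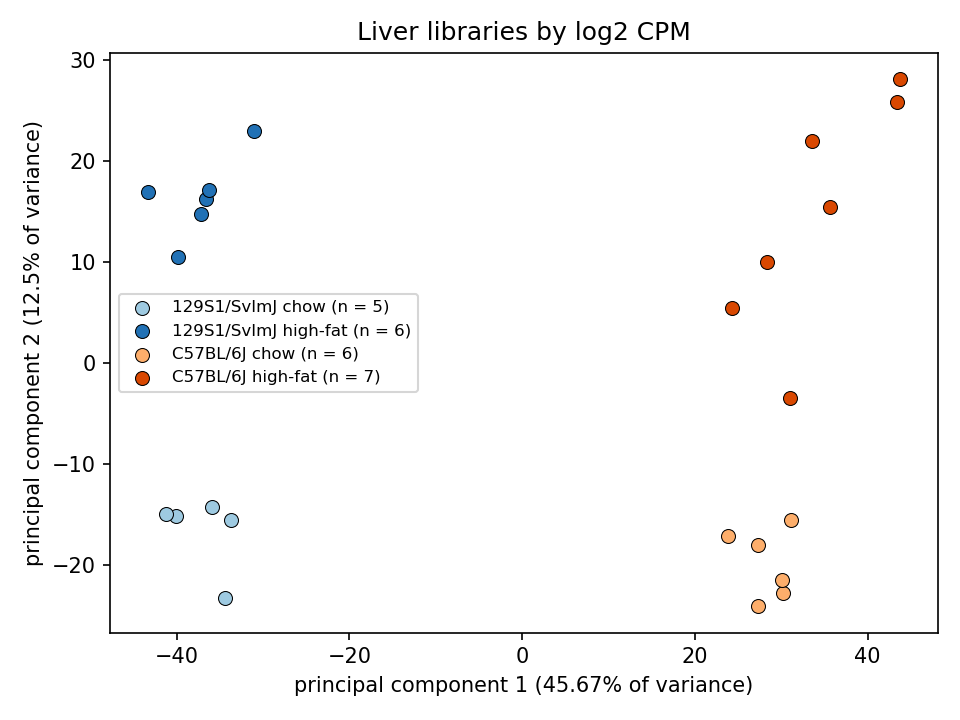
Scores of the 24 libraries on the first 2 principal components of log2 CPM, with 45.7% and 12.5% of the variance on the axes. Each point is 1 library, coloured by strain and diet.

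The first comparison asked which liver genes responded to the high-fat diet in 129S1/SvImJ (6 mice against 5 on chow). Genes of cholesterol synthesis were lower on high-fat diet by large factors. Sqle, which encodes squalene epoxidase (ENSMUSG00000022351.14, chromosome 15, 59315077 to 59331192, mm10), fell from 119.5 ± 27.1 CPM (SD, n = 5) to 0.663 ± 0.324 CPM (SD, n = 6), a log2 fold change of -7.40 (edgeR adjusted p = 1.09e-07). Idi1, of the isoprenoid branch of the pathway (ENSMUSG00000058258.14, chromosome 13, 8885501 to 8892451), fell from 31.1 ± 4.27 (SD, n = 5) to 1.91 ± 0.431 CPM (SD, n = 6), with edgeR adjusted p = 1.2e-11. Fads1, the delta-5 desaturase of polyunsaturated fatty acids (ENSMUSG00000010663.4, chromosome 19, 10182888 to 10196877), fell from 628.5 ± 71.6 (SD, n = 5) to 213.3 ± 9.42 CPM (SD, n = 6), with edgeR adjusted p = 2.78e-07. Nnmt, a methyltransferase of nicotinamide (ENSMUSG00000032271.13, chromosome 9, 48591877 to 48605153), rose from 3.29 ± 1.34 (SD, n = 5) to 22.2 ± 7.44 CPM (SD, n = 6), with edgeR adjusted p = 0.00203.

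Sult1e1, an estrogen sulfotransferase (ENSMUSG00000029272.8, chromosome 5, 87575969 to 87591594), rose by a log2 fold change of 4.74 (adjusted p = 0.000412), from 0.562 ± 0.283 (SD, n = 5) to 15.3 ± 10.5 CPM (SD, n = 6) by edgeR. The other named genes with large changes were Obp2a (3.00) and Tmem28 (3.00) among those that rose, and Mvd (-4.71) and Fdps (-4.26), both of cholesterol synthesis, among those that fell. For each of these genes the CPM of the chow and high-fat libraries did not overlap. Ces2b and Mup18 also rose but belong to families of near-identical genes, so their values are uncertain, and the call of Mup18 ended without chow replicate 1 (adjusted p = 0.0549) or 2 (0.051).

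All 24 tested genes of cholesterol synthesis and uptake fell, and 24 fell adjusted over the list alone, with a median log2 fold change of -2.04. The camera adjusted p was 4.83e-117, it was 4.97e-05 with an estimated correlation, and within the low and the high 7SK level it was 6.44e-152 and 4.74e-67. Nsdhl (-3.54) and Tm7sf2 (-2.25) are further examples. High-fat replicate 3 stood below its group for these genes (mean log2 CPM of 4.43 against 4.66 to 4.77), in the direction of the change. Without it the camera adjusted p was 8.55e-100. Of 24 genes of fatty acid and triglyceride synthesis 4 rose, 7 fell and the rest did not pass (5 and 8 adjusted over the list alone, median -0.25), and the list was not called (camera adjusted p = 0.0913, and 0.902 with an estimated correlation). It was called without chow replicate 1 (0.0495) or without high-fat replicate 5 of C57BL/6J (0.0422). The synthase gene Fasn (-1.58) and the acetyl-CoA synthetase gene Acss2 (-1.59) fell, and the acyltransferase gene Agpat2 (0.52) rose. Of 32 genes of fatty acid oxidation and PPARalpha targets 5 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.16, camera adjusted p = 0.00424, and 0.902 with an estimated correlation), with Acaa1b (1.05) and Ehhadh (0.88), both of peroxisomal oxidation, among those that rose. This call ended without chow replicate 5 (adjusted p = 0.058). High-fat replicate 3 stood above its group for these genes (mean log2 CPM of 6.95 against 6.71 to 6.76), and without it the adjusted p was 0.0225. Of 23 genes of lipid droplets and lipid uptake 4 rose and none fell (6 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.00482, and 0.902 with an estimated correlation). Among them were Hsd17b11 (0.95), Slc27a2 (0.61) and Fabp2 (0.83). The camera p within the high 7SK level was 0.695, 0.561 and 0.388 for fatty acid synthesis, oxidation and lipid droplets, against 0.00965, 3.85e-05 and 0.00016 within the low level.

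Of 72 nuclear genes of oxidative phosphorylation 8 rose and none fell (9 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 5.04e-05, and 0.902 with an estimated correlation), with Ndufb4 (0.66) and Cox5a (0.30) as examples. Of 36 genes of the urea cycle and amino acid breakdown 12 rose and none fell (12 and 0 adjusted over the list alone, median 0.08, camera adjusted p = 0.00131, and 0.902 with an estimated correlation). Among them were Aass (0.67), Kmo (0.54) and Bckdhb (0.35). Of 32 acute-phase genes 4 rose and 1 fell (6 and 2 adjusted over the list alone, median 0.21, camera adjusted p = 0.0181, and 0.902 with an estimated correlation). Saa4, a serum amyloid gene, rose (1.19) and Hamp, the gene of the iron hormone hepcidin, fell (-1.76). Of 17 markers of Kupffer cells, the resident macrophages, 1 rose (1 adjusted over the list alone, median 0.59, camera adjusted p = 0.00197, and 0.902 with an estimated correlation), and of 16 markers of recruited monocytes, macrophages and neutrophils 2 rose (2 adjusted over the list alone, median 0.82, camera adjusted p = 0.00354, and 0.902 with an estimated correlation), Mpeg1 (1.07) and Ccl6 (1.39). The Kupffer marker that rose was C1qa (0.72), whose call ended in 5 of the 24 fits without 1 library (adjusted p = 0.109 without chow replicate 1). Of 22 cell cycle genes 3 rose and none fell (3 adjusted over the list alone, median 0.37, camera adjusted p = 0.0445, and 0.902 with an estimated correlation). Of 82 ribosomal protein genes 1 fell and none rose (0 adjusted over the list alone, median -0.08, camera adjusted p = 0.0445, and 0.944 with an estimated correlation). Within the low 7SK level the camera p was 5.1e-08 for oxidative phosphorylation, 0.000119 for the urea cycle, 0.00034 for acute-phase genes, 0.00127 for Kupffer cells and 0.0992 for recruited cells, and within the high level 0.563, 0.399, 0.292, 0.00724 and 2.57e-05.

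Of 26 genes of the Wnt and TCF pathway, the pathway of the transcription factor TCF7L2 in the series title, 1 rose and 5 fell (1 and 6 adjusted over the list alone, median -0.25, camera adjusted p = 0.0344, and 0.902 with an estimated correlation). The receptor gene Fzd4 rose (0.95), and the co-receptor gene Lrp5 (-0.61) and the ligase gene Znrf3 (-0.43) fell. The list's call ended without chow replicate 1 (0.0949), 2 (0.236) or 5 (0.0742) and without high-fat replicate 2 (0.051), and its p was 0.03 and 0.731 within the low and high 7SK level. The feedback gene Axin2 (ENSMUSG00000000142.15, chromosome 11, 108920349 to 108950783) went from 21.02 ± 9.80 (SD, n = 5) to 10.2 ± 1.99 CPM (SD, n = 6), a log2 fold change of -1.03 (edgeR adjusted p = 0.0168), and this call ended without chow replicate 1 (0.059) or 2 (0.0695). Tcf7l2 itself (ENSMUSG00000024985.18, chromosome 19, 55741820 to 55933654) read 62.4 ± 7.46 (SD, n = 5) on chow and 52.5 ± 6.12 CPM (SD, n = 6) on high-fat diet, with edgeR adjusted p = 0.0783. It was called without chow replicate 3 (0.0247) or high-fat replicate 4 (0.0488), and within the low 7SK level (-0.472, 0.0137) but not the high level (-0.00147, 0.999).

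In all, 1514 of 14533 genes were called for diet in 129S1/SvImJ, 786 higher and 728 lower on high-fat diet. Without chow replicate 1 the number was 937. Within the low 7SK level 850 genes were called and within the high level 172, and without both libraries with adipocyte transcripts 1075. Of the 47 named genes called, 38 kept their call in every fit without 1 library, 39 were called within the low level and 11 within the high level.

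The second comparison asked the same of C57BL/6J (7 mice on high-fat diet, 6 on chow). Of the genes of cholesterol synthesis and uptake 22 of 24 fell, and of the ribosomal protein genes 64 of 82. Of the genes of lipid droplets and lipid uptake 13 of 23 rose, a list not called with an estimated correlation (adjusted p = 0.109). It was called with fry (adjusted p = 0.000231). Cfd, the serum protease adipsin best known from fat tissue (ENSMUSG00000061780.6, chromosome 10, 79890853 to 79892655), rose from 3.53 ± 3.53 (SD, n = 6) to 147.1 ± 79.8 CPM (SD, n = 7), a log2 fold change of 5.35 (edgeR adjusted p = 1.17e-05). Cidec, of lipid droplet fusion (ENSMUSG00000030278.11, chromosome 6, 113424634 to 113435760), rose from 5.37 ± 1.65 (SD, n = 6) to 89.4 ± 70.4 CPM (SD, n = 7), with edgeR adjusted p = 2.64e-05. Cd36, a fatty acid transporter (ENSMUSG00000002944.15, chromosome 5, 17781690 to 17888801), rose from 48.0 ± 8.63 (SD, n = 6) to 203.9 ± 107 CPM (SD, n = 7), with edgeR adjusted p = 2.54e-05. Sqle fell from 115.8 ± 35.9 (SD, n = 6) to 6.79 ± 6.26 CPM (SD, n = 7), with edgeR adjusted p = 3.23e-06.

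**Figure D2:**
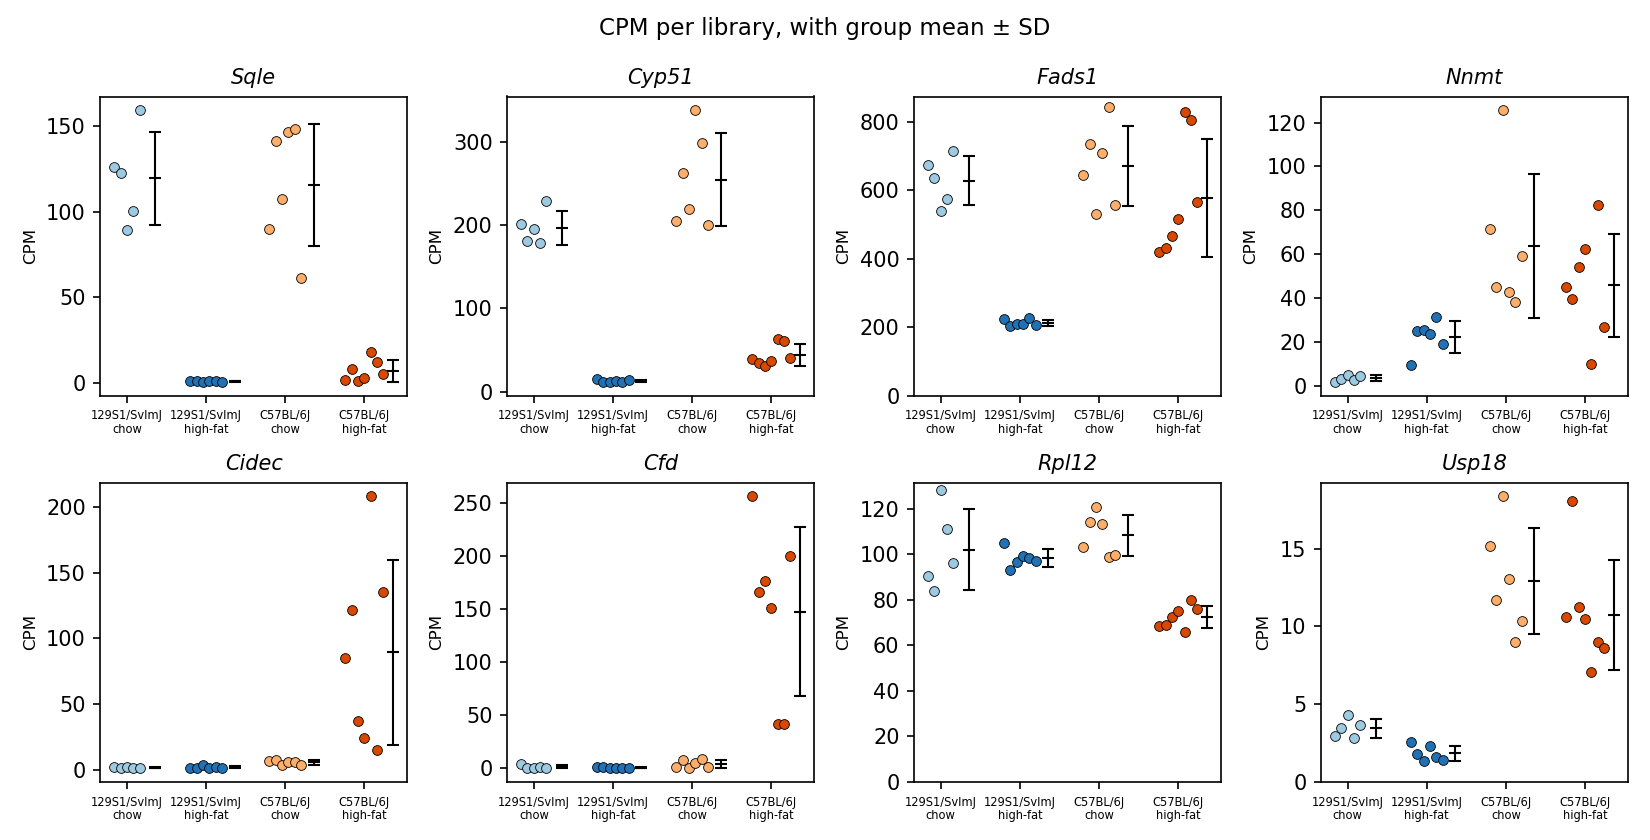
CPM of single libraries for 8 genes, by strain and diet, with the mean and SD of each group. Sqle was lower on high-fat diet in both strains, while Cidec read 89.4 ± 70.4 CPM in C57BL/6J on high-fat diet and 1.82 ± 0.927 CPM in 129S1/SvImJ on high-fat diet.

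Adam11 (ENSMUSG00000020926.16, chromosome 11, 102761439 to 102780262) rose from 12.7 ± 2.88 (SD, n = 6) to 86.5 ± 29.5 CPM (SD, n = 7) in C57BL/6J, a log2 fold change of 2.77 (edgeR adjusted p = 7.58e-09), and in 129S1/SvImJ by 2.40 (1.48e-07). Themis (3.53) and the apolipoprotein gene Apoa4 (3.09) also rose, and Fabp5 (-2.71) and Adgrf1 (-2.69) fell. Cyp2a22 rose too but belongs to a family of near-identical genes. Pparg, a regulator of fat storage (ENSMUSG00000000440.12, chromosome 6, 115360951 to 115490399), rose from 11.6 ± 4.32 (SD, n = 6) to 28.2 ± 14.4 CPM (SD, n = 7), with edgeR adjusted p = 0.00434. Tcf7l2 fell from 58.3 ± 4.86 (SD, n = 6) to 47.7 ± 4.91 CPM (SD, n = 7), a log2 fold change of -0.29 (edgeR adjusted p = 0.0169, at most 0.0498 without any 1 library), and was not called within the low (-0.239, 0.245) or the high 7SK level (-0.258, 0.113). Axin2 read 16.8 ± 3.99 (SD, n = 6) and 17.0 ± 4.55 CPM (SD, n = 7), with edgeR adjusted p = 0.974.

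Of the 24 genes of cholesterol synthesis and uptake 22 fell and none rose (22 adjusted over the list alone, median -1.46, camera adjusted p = 1.39e-59, and 0.00415 with an estimated correlation), with Idi1 (-3.36), Cyp51 (-2.54) and Hsd17b7 (-1.70) as examples. Of 82 ribosomal protein genes 64 fell and none rose (73 adjusted over the list alone, median -0.34, camera adjusted p = 6.38e-45, and 0.042 with an estimated correlation). Rpl12 (-0.58) was among them. Of 23 genes of lipid droplets and lipid uptake 13 rose and none fell (14 adjusted over the list alone, median 0.63, camera adjusted p = 8.2e-13, and 0.109 with an estimated correlation). Fabp2 (1.63) and Hsd17b11 (0.68) rose with Cd36. Of 13 adipocyte genes listed only 4 passed the count filter, without Adipoq, Lep, Plin1 or Retn. All 4 rose (4 adjusted over the list alone, median 3.47), with Fabp4 (1.59) and Cidea (7.71) beside Cfd and Lipe, and no set test was run on so few. A gene can pass the filter through the group where it is high, as Cfd is here, so the shared direction is no separate evidence. High-fat replicate 5 held transcripts of the fat-cell genes Adipoq (1.23 CPM), Lep (3.28 CPM) and Plin1 (1.56 CPM). Within the low and high 7SK level the camera p was 8.68e-93 and 1.32e-33 for cholesterol synthesis, 7.86e-22 and 2.5e-52 for ribosomal proteins, and 6.55e-11 and 1.03e-08 for lipid droplets.

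Of 32 genes of fatty acid oxidation and PPARalpha targets 10 rose and none fell (16 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.000123, and 0.72 with an estimated correlation). Among them were Acaa1b (1.13) and Acot2 (1.49). Of 24 genes of fatty acid and triglyceride synthesis 7 rose and 1 fell (9 and 2 adjusted over the list alone, median 0.12, camera adjusted p = 0.0124, and 0.727 with an estimated correlation), with the regulator Srebf1 (1.40) and Scd1 (1.35) among those that rose. That call ended without chow replicate 3 (0.0707) or high-fat replicate 5 (0.102). Of 22 cell cycle genes 12 rose and none fell (16 adjusted over the list alone, median 0.78, camera adjusted p = 8.64e-06, and 0.572 with an estimated correlation). Among them were Mcm4 (0.93), Bub1b (1.48) and the inhibitor gene Cdkn1a (1.94). Of 29 stellate cell and fibrosis genes 7 rose and none fell (12 adjusted over the list alone, median 0.42, camera adjusted p = 0.00126, and 0.74 with an estimated correlation), Col5a2 among them (1.40). The calls of Col5a1 and Col6a1 ended in 6 and that of Col3a1 in 4 of the 24 fits without 1 library, and all 3 ended without both libraries with adipocyte transcripts (0.0662, 0.0689 and 0.09). Of 24 antioxidant and NRF2 target genes 5 rose and none fell (6 adjusted over the list alone, median 0.21, camera adjusted p = 0.00728, and 0.72 with an estimated correlation), with Nqo1 (0.86) and Taldo1 (0.37) as examples. Of 16 markers of recruited monocytes, macrophages and neutrophils 2 rose and none fell (4 adjusted over the list alone, median 0.41, camera adjusted p = 0.0271, and 0.793 with an estimated correlation). Of 72 nuclear genes of oxidative phosphorylation 4 rose and none fell (4 adjusted over the list alone, median 0.10, camera adjusted p = 0.0126, and 0.821 with an estimated correlation). The camera p within the low and high 7SK level was 0.0175 and 2.54e-05 for fatty acid oxidation, 0.48 and 0.000448 for fatty acid synthesis, 0.000238 and 0.000376 for the cell cycle, 0.0154 and 0.000832 for fibrosis, and 0.00126 and 0.0532 for antioxidant genes.

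Of 22 genes with higher expression in male liver 6 fell and none rose (6 adjusted over the list alone, median -0.42, camera adjusted p = 9.41e-05, and 0.706 with an estimated correlation). Among them were Susd4 (-1.47), Elovl3 (-1.12) and Gstp1 (-0.91). Within the low and high 7SK level its p was 0.0775 and 9.32e-08. Of 26 genes of the Wnt and TCF pathway 1 rose and 4 fell (1 and 5 adjusted over the list alone, median -0.05, camera adjusted p = 0.0437, and 0.572 with an estimated correlation). Fzd4 rose (0.61), and Znrf3 (-0.45), Tcf7 (-0.87) and Notum (-0.63) fell, as in 129S1/SvImJ for Fzd4 and Znrf3. The list's call ended in 12 of the 24 fits without 1 library (p of 0.0508 to 0.116). These were without chow replicate 1, 2, 3, 4 or 5 or high-fat replicate 4 of 129S1/SvImJ, and without chow replicate 1, 2 or 5 or high-fat replicate 4, 6 or 7 of C57BL/6J. Its p was 0.025 and 0.438 within the low and high 7SK level.

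In all, 2159 of 14533 genes were called for diet in C57BL/6J, 1113 higher and 1046 lower on high-fat diet, of which 217 and 98 by at least 2-fold. Within the low 7SK level, with 2 libraries on high-fat diet, 374 genes were called, and within the high level 746.

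The third comparison asked how the strains differed on chow (129S1/SvImJ, 5 mice, against C57BL/6J, 6 mice). Of the interferon response genes 35 of 43 were lower in 129S1/SvImJ, and of the Kupffer cell markers 14 of 17, but neither list was called with an estimated correlation (adjusted p = 0.761 and 0.946). Both lists were called with fry (adjusted p = 0.000159 and 0.00404). Oasl1, an interferon-induced gene (ENSMUSG00000041827.15, chromosome 5, 114923240 to 114937915), read 2.73 ± 0.986 (SD, n = 5) in 129S1/SvImJ and 15.4 ± 4.58 CPM (SD, n = 6) in C57BL/6J, a log2 fold change of -2.48 (edgeR adjusted p = 1.63e-08). Usp18, a brake on interferon signalling (ENSMUSG00000030107.10, chromosome 6, 121245906 to 121270917), read 3.45 ± 0.601 (SD, n = 5) and 12.9 ± 3.42 CPM (SD, n = 6), with edgeR adjusted p = 3e-07. Ctse, the aspartic protease cathepsin E (ENSMUSG00000004552.16, chromosome 1, 131638306 to 131675505), was higher in 129S1/SvImJ, with 37.3 ± 4.49 (SD, n = 5) against 0.232 ± 0.116 CPM (SD, n = 6) and edgeR adjusted p = 2.43e-12.

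Some genes had counts in 1 strain and none in the other. Myom2, of the sarcomere (ENSMUSG00000031461.4, chromosome 8, 15057653 to 15133541), read 12.6 ± 0.642 CPM (SD, n = 5) in 129S1/SvImJ and 0 in C57BL/6J, at least 283-fold higher against a floor of 3 counts over the group. Trim12a (ENSMUSG00000066258.13, chromosome 7, 104299894 to 104315466) read 0 in 129S1/SvImJ and 12.8 ± 1.38 CPM (SD, n = 6) in C57BL/6J, at least 177-fold lower, and has close relatives, so its value is uncertain. Rn7s2, a copy of the 7SL RNA gene (ENSMUSG00000099250.1, chromosome 12, 69361182 to 69361481, misc_RNA), read 302.2 ± 140 CPM (SD, n = 5) in 129S1/SvImJ and 0 in C57BL/6J, at least 6770-fold higher, and is uncertain since its copies are near-identical. Acpp had 1 count over the group in 129S1/SvImJ and read 13.01 ± 6.43 CPM (SD, n = 6) in C57BL/6J. Serpina1e, Mup11, Mup20, Ugt2b38 and Cyp2a4 also differed and are uncertain for the same reason. Scd1 (ENSMUSG00000037071.2, chromosome 19, 44394455 to 44407879) read 5799 ± 881 (SD, n = 5) in 129S1/SvImJ and 16580.0 ± 7120.0 CPM (SD, n = 6) in C57BL/6J, a log2 fold change of -1.52 (edgeR adjusted p = 0.000296). Cd36 (-1.04) and Pparg (-1.65) were lower in 129S1/SvImJ as well, and Tcf7l2 differed by 0.10 (adjusted p = 0.471).

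Of 43 interferon response genes 35 were lower and none higher in 129S1/SvImJ (37 and 1 adjusted over the list alone, median -1.10, camera adjusted p = 4.69e-14, and 0.761 with an estimated correlation), with Irf7 (-1.46) and Ifi27 (-1.10) as further examples. Of 17 Kupffer cell markers 14 were lower and 1 higher (14 and 1 adjusted over the list alone, median -1.13, camera adjusted p = 3.98e-06, and 0.946 with an estimated correlation). Among them were C1qa (-1.75), Vsig4 (-1.55) and Cd68 (-1.38). Of 12 lymphocyte markers 8 were lower and none higher (9 adjusted over the list alone, median -1.32, camera adjusted p = 0.00292, and 0.761 with an estimated correlation). Among them were the B cell genes Cd79a (-2.67) and Ighm (-2.14). Of 16 markers of recruited monocytes, macrophages and neutrophils 7 were lower and none higher (8 adjusted over the list alone, median -0.90, camera adjusted p = 0.00666, and 0.946 with an estimated correlation), with Cd44 (-1.87) and Mpeg1 (-1.63) as examples. Within the low and high 7SK level the camera p was 1.82e-07 and 4.66e-27 for interferon genes, 1.82e-07 and 3.87e-08 for Kupffer cells, 0.0132 and 0.000663 for lymphocytes, and 0.0175 and 0.000523 for recruited cells. Of 22 genes with higher expression in male liver 7 were lower and 1, Cyp4a12a, higher (8 and 1 adjusted over the list alone, median -0.26, mean -1.54, camera adjusted p = 0.0198, 0.946 with an estimated correlation, 0.0477 and 0.000523 within the 7SK levels). Cyp4a12a and the Mup and Ugt2b genes of this list belong to families of near-identical genes, so their values and the list's call are uncertain. Of 28 genes of the unfolded protein and integrated stress response 12 were lower and none higher (12 adjusted over the list alone, median -0.36). Among them were the chaperone genes Dnajb11 (-0.59), Hyou1 (-0.98) and Calr (-0.40). The list was not called (camera adjusted p = 0.0543, and 0.946 with an estimated correlation, 0.0993 and 0.0549 within the 7SK levels), but was called in 7 of the 24 fits without 1 library (p of 0.00437 to 0.0414). These were without chow replicate 1 or 3 of 129S1/SvImJ, or chow replicate 2, 4 or 5 or high-fat replicate 1 or 5 of C57BL/6J.

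In all, 3636 of 14533 genes were called between the strains on chow, 1825 higher and 1811 lower in 129S1/SvImJ, of which 428 and 669 by at least 2-fold. Loss of 129S1/SvImJ reads in mapping to mm10 would lower genes in that strain. It was not tested for these counts or for the genes with no counts in 129S1/SvImJ. Within the low 7SK level 2123 were called and within the high level 1346.

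The fourth comparison asked how the strains differed on high-fat diet (129S1/SvImJ, 6 mice, against C57BL/6J, 7 mice). Of the interferon response genes 34 of 43 were lower in 129S1/SvImJ, and of the ribosomal protein genes 53 of 82 were higher, but neither list was called with an estimated correlation (adjusted p = 0.718 for each). Both lists were called with fry (adjusted p = 5.46e-05 and 0.000195). Cfd read 0.081 ± 0.0996 (SD, n = 6) in 129S1/SvImJ and 147.1 ± 79.8 CPM (SD, n = 7) in C57BL/6J, with edgeR adjusted p = 4.24e-08. Cidec read 1.82 ± 0.927 (SD, n = 6) and 89.4 ± 70.4 CPM (SD, n = 7), a log2 fold change of -5.61 (edgeR adjusted p = 2.12e-07). Oasl1 read 2.12 ± 0.624 (SD, n = 6) and 17.1 ± 3.11 CPM (SD, n = 7), a log2 fold change of -2.98 (edgeR adjusted p = 6.98e-11). Fads1 read 213.3 ± 9.42 (SD, n = 6) and 576.6 ± 173 CPM (SD, n = 7), with edgeR adjusted p = 2.79e-08.

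Myom2 was at least 400-fold higher in 129S1/SvImJ, and Trim12a at least 294-fold, Cebpe at least 160-fold and Zfp982 at least 152-fold lower, the last 2 also with no counts in 129S1/SvImJ. Pde6h (426 counts over the group in 129S1/SvImJ and 2 in C57BL/6J) and the renin gene Ren1 (426 and 4), which has a close copy in some strains and is uncertain, were higher in 129S1/SvImJ. Cd36 (-2.21), Pparg (-2.76) and Scd1 (-1.81) were lower, as on chow. The bile acid gene Cyp7a1 was higher (1.20, adjusted p = 0.0137), and the pericentral gene Glul was lower (-0.46, adjusted p = 0.011). Tcf7l2 differed by 0.14 (adjusted p = 0.179), by -0.134 (0.432) within the low 7SK level and by 0.316 within the high level, where it was called (0.0238). Axin2 was lower (-0.73, adjusted p = 0.0269), a call that ended in 5 of the 24 fits without 1 library (0.0616 without high-fat replicate 4 of 129S1/SvImJ).

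Of 43 interferon response genes 34 were lower and 1 higher (36 and 1 adjusted over the list alone, median -1.06, camera adjusted p = 3.2e-12, and 0.718 with an estimated correlation), with Usp18 (-2.52) and Irf7 (-1.58). High-fat replicate 2 of C57BL/6J stood above its group for these genes (mean log2 CPM of 4.61 against 3.69 to 4.03), in the direction of this difference, and without it the adjusted p was 2.17e-12. Of 82 ribosomal protein genes 53 were higher and 4 lower (59 and 4 adjusted over the list alone, median 0.26, camera adjusted p = 2.18e-08, and 0.718 with an estimated correlation). Rps7 (0.77) and Rpl15 (0.91) were higher and Rpl34 (-0.68) was lower. On chow 6 of these genes were higher and 6 lower, and the list was not called (median 0.004, camera adjusted p = 0.629). The diet effect in C57BL/6J was -0.294 for Rpl15 and -0.363 for Rpl34, and in the other strain -0.0494 and -0.108. These were small beside the strain differences of Rpl15 and Rpl34, which therefore cannot be read as diet responses. Of 24 genes of fatty acid and triglyceride synthesis 16 were lower and 2 higher (16 and 2 adjusted over the list alone, median -0.80, camera adjusted p = 0.000223, and 0.718 with an estimated correlation). Among them were Acacb (-2.57), Elovl6 (-1.69) and Fads2 (-1.49). High-fat replicate 5 of C57BL/6J, which held adipocyte transcripts, stood above its group for these genes (mean log2 CPM of 8.73 against 7.99 to 8.29), in the direction of this difference, and without it the adjusted p was 0.000167. Of 24 genes of cholesterol synthesis and uptake 14 were lower and 1 higher (15 and 1 adjusted over the list alone, median -0.56, camera adjusted p = 0.000355, and 0.718 with an estimated correlation). Among them were Cyp51 (-1.75) and Hmgcs1 (-1.81). Of 23 genes of lipid droplets and lipid uptake 14 were lower and 2 higher (15 and 3 adjusted over the list alone, median -0.72, camera adjusted p = 0.000502, and 0.718 with an estimated correlation). Among them were Fitm1 (-2.46) and Fabp2 (-1.08). All 4 tested adipocyte genes, of 13 listed, were lower (median -5.51), Lipe by -0.89, with the same limit from the count filter. Of 36 genes of the urea cycle and amino acid breakdown 19 were higher and 1 lower (19 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.000313, and 0.718 with an estimated correlation). Among them were Bckdhb (0.77) and Prodh (0.66). The camera p within the low and high 7SK level was 3.01e-18 and 1.13e-10 for interferon, 1.19e-05 and 1.13e-10 for ribosomal proteins, 7.52e-06 and 0.00191 for fatty acid synthesis, 0.00121 and 0.0015 for cholesterol, 0.00155 and 0.00052 for lipid droplets, and 0.000461 and 0.00253 for the urea cycle.

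Of 21 genes of bile acid synthesis and transport 10 were higher and 2 lower (10 and 2 adjusted over the list alone, median 0.36, camera adjusted p = 0.016, and 0.718 with an estimated correlation). Among them were Acox2 (1.11), the transporter gene Slc10a1 (0.69) and Cyp7b1 (1.75). Of 29 stellate cell and fibrosis genes 15 were lower and 3 higher (18 and 3 adjusted over the list alone, median -0.77, camera adjusted p = 0.00548, and 0.759 with an estimated correlation). Among them were Col6a3 (-1.92) and Thbs1 (-2.13). Of 20 immediate early genes 9 were lower and 1 higher (11 and 1 adjusted over the list alone, median -0.62, camera adjusted p = 0.028, and 0.718 with an estimated correlation). Among them were Jund (-0.58) and Fos (-1.30). Of 12 lymphocyte markers 9 were lower and none higher (9 adjusted over the list alone, median -1.17, camera adjusted p = 0.0181, and 0.718 with an estimated correlation). Of 17 Kupffer cell markers 10 were lower and none higher (11 and 1 adjusted over the list alone, median -0.74, camera adjusted p = 0.0188, 0.759 with an estimated correlation, and 0.0519 without high-fat replicate 3 of 129S1/SvImJ). Among them were C1qa (-1.15) and Marco (-2.41). High-fat replicate 2 of C57BL/6J, 1 of the 2 libraries of its group in the low 7SK level, stood above its group for these markers (mean log2 CPM of 5.33 against 4.19 to 4.63), in the direction of this difference, and without it the adjusted p was 0.0363. Of the 16 markers of recruited monocytes, macrophages and neutrophils 7 were lower and none higher (7 adjusted over the list alone, median -0.75, camera adjusted p = 0.03, and 0.759 with an estimated correlation). Of 22 cell cycle genes 13 were lower and 1 higher (13 and 3 adjusted over the list alone, median -0.96, camera adjusted p = 0.0226, and 0.759 with an estimated correlation). Among them were Mcm6 (-2.80) and Ccnd1 (-1.79), and this call ended without high-fat replicate 2 (0.0539) or 5 (0.0627) of C57BL/6J. Of 12 cholangiocyte markers 6 were lower and none higher (7 adjusted over the list alone, median -1.10, camera adjusted p = 0.0377, and 0.718 with an estimated correlation). Among them were Sox9 (-1.69) and Spp1 (-1.80), and this call ended without high-fat replicate 3 (0.0519) or 6 (0.0558) of 129S1/SvImJ or replicate 5 of C57BL/6J (0.0592). Within the low and high 7SK level the camera p was 0.00497 and 0.0514 for bile acids, 0.00244 and 0.0228 for fibrosis, 0.0187 and 0.0424 for immediate early genes, 0.00369 and 0.0429 for lymphocytes, 2.53e-07 and 0.288 for Kupffer cells, 0.0261 and 0.0424 for the cell cycle, and 0.0629 and 0.0209 for cholangiocytes.

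In all, 5375 of 14533 genes were called between the strains on high-fat diet, 2600 higher and 2775 lower in 129S1/SvImJ, of which 444 and 901 by at least 2-fold. As on chow, loss of 129S1/SvImJ reads in mapping was not tested for these counts or for the genes with no counts in that strain. Within the low 7SK level 2369 were called and within the high level 3138.

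The fifth comparison tested whether the diet effect itself differed between the strains (the effect in 129S1/SvImJ minus that in C57BL/6J). Of the genes of cholesterol synthesis and uptake 3 of 24 had a lower diet effect in 129S1/SvImJ past the test, and the list was not called with an estimated correlation (adjusted p = 0.349). Nor was the list called with fry (adjusted p = 0.0823). For Fads1 the diet effect was -1.56 in 129S1/SvImJ and -0.22 in C57BL/6J, an interaction of -1.34 on the log2 scale (edgeR adjusted p = 0.0082, at most 0.0295 without any 1 library). For the lanosterol demethylase gene Cyp51 (ENSMUSG00000001467.5, chromosome 5, 4081145 to 4104746) it was -3.93 and -2.54, an interaction of -1.38 (edgeR adjusted p = 0.0182, at most 0.0401 without any 1 library). Crybg3 (ENSMUSG00000022723.15, chromosome 16, 59490775 to 59600979) read 10.4 ± 1.21 (SD, n = 5) and 11.1 ± 1.37 CPM (SD, n = 6) on chow and high-fat diet in 129S1/SvImJ and 32.2 ± 4.48 (SD, n = 6) and 19.3 ± 2.61 CPM (SD, n = 7) in C57BL/6J, an interaction of 0.82 (edgeR adjusted p = 0.0196, at most 0.0455 without any 1 library). These 3 were the named interaction genes called without each library in turn. Without both libraries with adipocyte transcripts Fads1 was called (0.0186) and Cyp51 and Crybg3 were not (0.0509 for each), and none of the 3 was called within either 7SK level.

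Nnmt (3.26) was also called and lost its call in 16 of the 24 fits without 1 library (adjusted p = 0.113 without chow replicate 2 of 129S1/SvImJ). Several genes called for diet in C57BL/6J and not in 129S1/SvImJ were not shown to differ in their diet effect, among them Cidec (interaction adjusted p = 0.134), Cd36 (0.165) and Pparg (0.315). Cd36, with adjusted p = 0.0532 for diet in 129S1/SvImJ, was called there in 4 of the 24 fits without 1 library (0.0207 to 0.0444). The interaction of Cfd had an edgeR unadjusted p of 0.00315 and did not pass after adjustment. Neither did those of Sqle (adjusted p = 0.0773), Tcf7l2 (0.91) and Axin2 (0.176).

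Of 82 ribosomal protein genes 7 had a higher diet effect in 129S1/SvImJ and none a lower one (51 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 4.08e-30, and 0.349 with an estimated correlation). Of 24 genes of cholesterol synthesis and uptake 3 were lower and none higher (14 and 1 adjusted over the list alone, median -0.71, camera adjusted p = 1.25e-16, and 0.349 with an estimated correlation). High-fat replicate 3 of 129S1/SvImJ stood below its group for these genes, in the direction of this difference, and without it the camera adjusted p was 4.01e-14. Of 24 genes of fatty acid and triglyceride synthesis 1, Fads1, was lower (6 adjusted over the list alone, median -0.42, camera adjusted p = 1.6e-06, and 0.541 with an estimated correlation). Of 143 genes of families with near-identical copies 1 was lower and none higher. No gene of the male-biased, urea cycle, acute-phase, fibrosis, lipid droplet or Kupffer cell lists was called alone. The 22 genes with higher expression in male liver had a median of 0.71 (0 adjusted over the list alone, camera adjusted p = 4.62e-08, and 0.567 with an estimated correlation), with Susd4 at 1.02. The 36 genes of the urea cycle and amino acid breakdown had a median of 0.21 (9 higher adjusted over the list alone, camera adjusted p = 1.27e-07, and 0.567 with an estimated correlation), with Aass at 0.60. The 32 acute-phase genes had a median of 0.52 (6 higher adjusted over the list alone, camera adjusted p = 6.68e-05, and 0.567 with an estimated correlation), with Itih3 at 0.75. Chow replicate 3 of C57BL/6J stood above its group for these genes (mean log2 CPM of 7.79 against 6.39 to 6.72) and for Itih3 (1300 against 619 to 808 CPM), in the direction of this difference. Without it the list's adjusted p was 0.0129 and Itih3 was at 0.567. The camera p within the low and high 7SK level was 8.74e-25 and 2.59e-14 for ribosomal proteins, 1.6e-13 and 6.23e-10 for cholesterol, 6.93e-05 and 2.28e-05 for fatty acid synthesis, 1.37e-06 and 2.62e-06 for male-biased genes, 1.39e-08 and 0.00665 for the urea cycle, and 0.159 and 9.51e-06 for acute-phase genes.

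The 29 stellate cell and fibrosis genes had a median interaction of -0.70 (5 lower adjusted over the list alone, camera adjusted p = 3.29e-05, and 0.67 with an estimated correlation), with Col5a1 at -0.99. The 23 genes of lipid droplets and lipid uptake had a median of -0.47 (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.000691, and 0.618 with an estimated correlation), with Fabp2 at -0.81. The 17 Kupffer cell markers had a median of 0.45 (0 adjusted over the list alone, camera adjusted p = 0.00074, and 0.735 with an estimated correlation), with Fcna at 0.70. Within the low and high 7SK level the camera p was 1.73e-06 and 0.167 for fibrosis, 0.0803 and 8.65e-05 for lipid droplets, and 0.79 and 6.23e-10 for Kupffer cells, whose direction was the opposite within the low level.

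**Figure D3:**
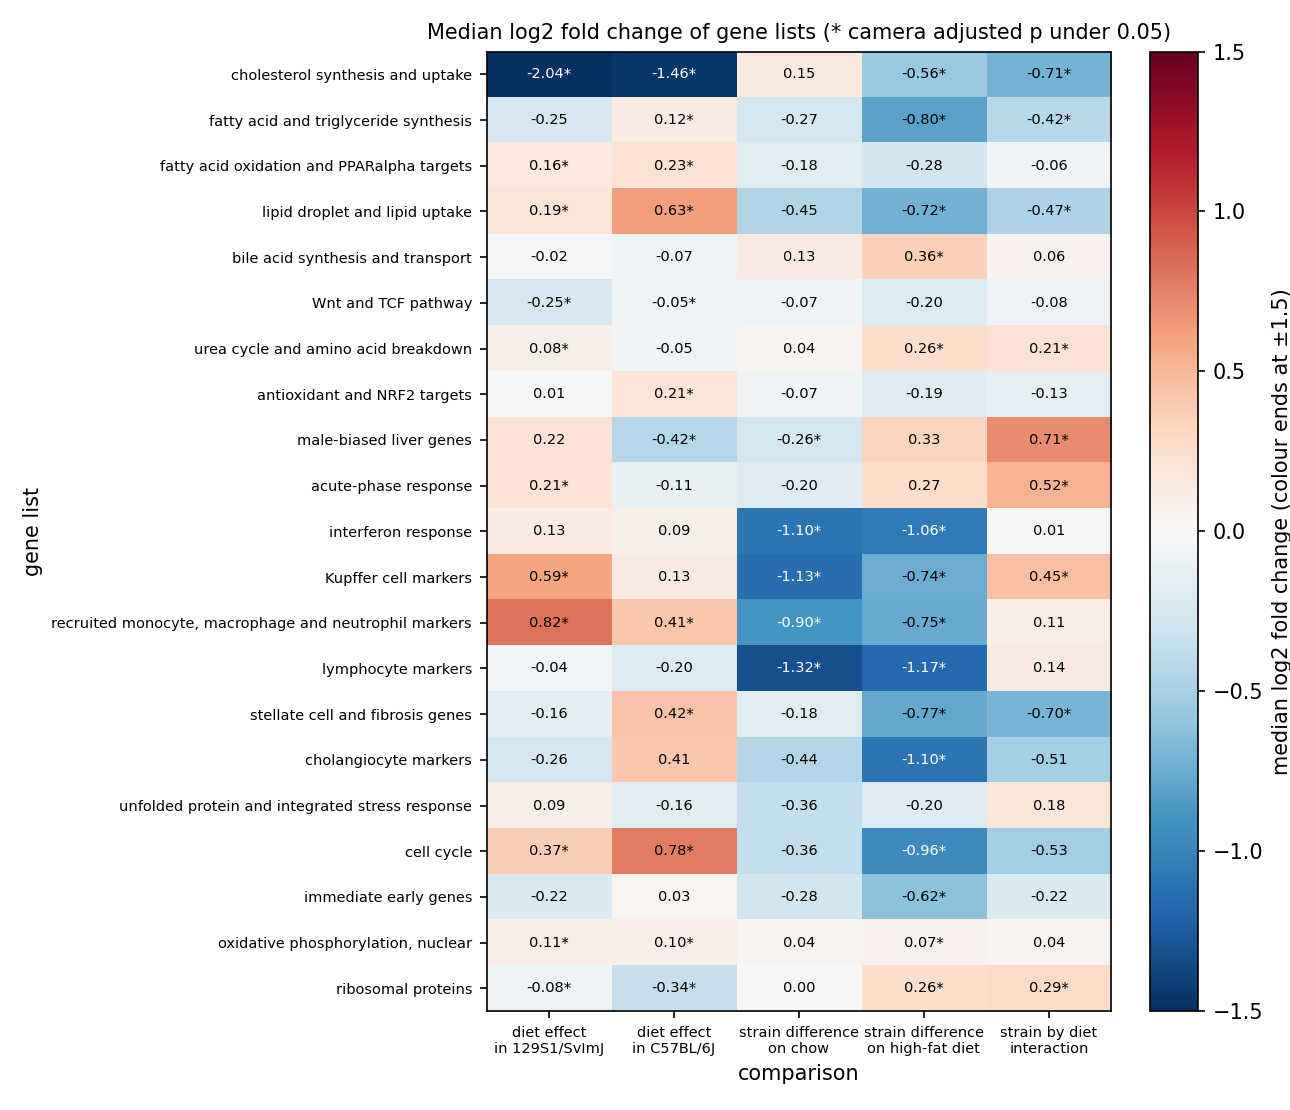
Median log2 fold change of the tested members of gene lists (vertical) in the 5 comparisons (horizontal), with the value written in each cell. Cholesterol synthesis and uptake had a median of -2.04 for diet in 129S1/SvImJ and -1.46 in C57BL/6J, and ribosomal proteins -0.34 for diet in C57BL/6J.

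In all, 43 of 14533 genes were called in the interaction, 25 higher and 18 lower, of which 5 and 10 by at least 2-fold. By edgeR 2077 genes had an unadjusted p under 0.05. The number depended on single libraries. In 129S1/SvImJ it was 5, 6, 103 and 21 without chow replicate 1, 2, 4 and 5, and 25, 16, 20, 16, 18 and 18 without high-fat replicate 1, 2, 3, 4, 5 and 6. In C57BL/6J it was 15, 14, 79 and 13 without chow replicate 2, 3, 5 and 6, and 12, 14, 22, 170, 23, 101 and 16 without high-fat replicate 1, 2, 3, 4, 5, 6 and 7. Within the low 7SK level 1 gene was called and within the high level 0 by edgeR, with 1080 and 1240 genes at an unadjusted p under 0.05, and 91 with the level as a term. Without both libraries with adipocyte transcripts 2 genes were called.

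Across the 14533 genes, which are not independent replicates, the log2 diet effects of the strains had a Pearson correlation of 0.439 and a Spearman correlation of 0.397, and the comparisons share no library. Of the genes called in both strains, 311 were higher in both (60.2 by chance), 274 lower in both (52.4 by chance) and 3 opposite. The strain differences on chow and on high-fat diet had a Pearson correlation of 0.872 and a Spearman correlation of 0.673, with 1244 genes higher in both (326 by chance), 1365 lower in both (346 by chance) and 11 opposite.

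**Figure D4:**
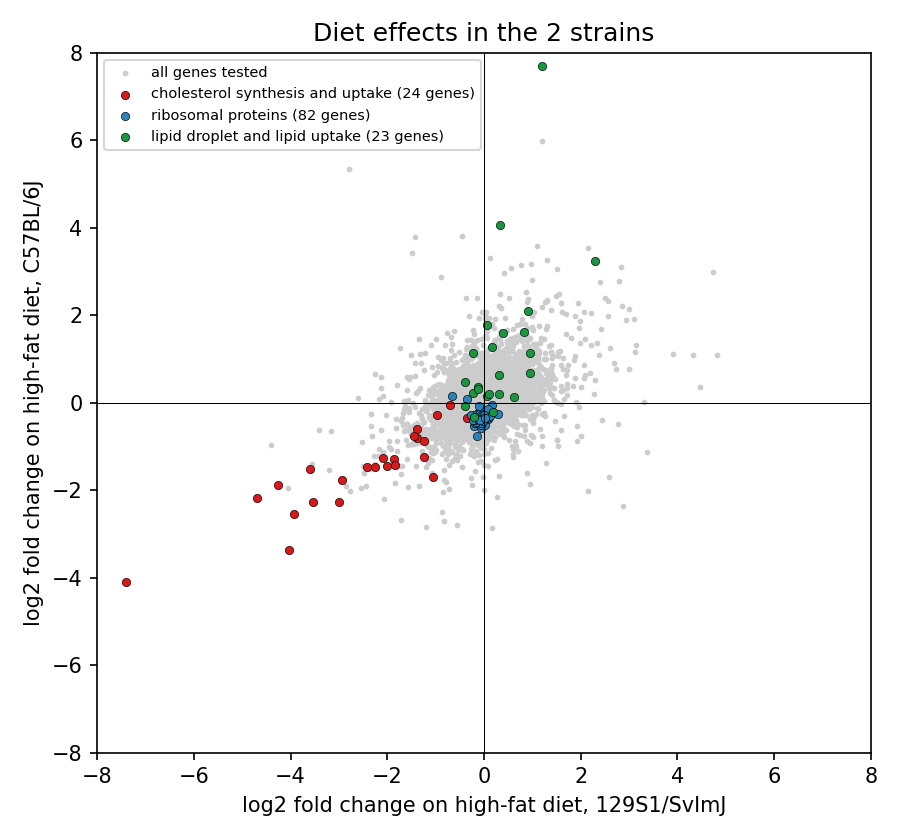
Log2 fold change on high-fat diet in 129S1/SvImJ (horizontal) against C57BL/6J (vertical) for the 14533 genes tested, with members of 3 gene lists coloured. The Pearson correlation across genes was 0.439.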

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

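The tests on genes matched in length and GC content and on the neighbours of interferon genes were written before their results were seen, and all other tests here were chosen after the result was seen. The bootstrap SEs come from resampling genes, which are not independent, and hold no spread between mice.

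Ribosomal protein genes were lower on high-fat diet in C57BL/6J (median log2 fold change -0.345, 64 of 82 called). No single library carried this, since at least 58 of the 82 genes were called lower without any 1 library. The 602 genes matched in length, GC content and expression had a median of 0.0344 ± 0.0093 (bootstrap SE), which argues against a length or GC bias. With the 7SK level as a term the median was -0.369 ± 0.0092 (bootstrap SE), so taking out the level did not weaken the pattern. A lower abundance of these messages on high-fat diet may be a response of the C57BL/6J liver, and unequal handling of the diet groups stays open because the labels give no batch.

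Interferon response genes were lower in 129S1/SvImJ on chow (median -1.10, 35 of 43 called). Mapping lost over the whole 129S1/SvImJ haplotype around these genes would lower their neighbours too. The 721 tested genes within 1 Mb had a median of -0.00961 ± 0.0107 (bootstrap SE), which argues against loss spread over these regions. Loss confined to the interferon genes themselves would not show in their neighbours, so this test cannot decide it and it stays open. A general lack of cells other than hepatocytes would lower endothelial markers, whose median was -0.0365 ± 0.0416 (bootstrap SE, 24 genes). Fewer immune cells stay open, since Kupffer cell (-1.13) and lymphocyte (-1.32) markers were lower alongside. A strain difference in the interferon response itself may also account for it and was not tested apart from the number of immune cells.

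Cfd and Cidec were higher on high-fat diet in C57BL/6J (log2 fold changes 5.35 and 4.06). Adipose tissue in the samples would bring Adipoq, which stood below 0.01 of Cfd in 6 of the 7 libraries, and this argues against adipose tissue as the source there. High-fat replicate 5 was the exception, with Adipoq at 1.23 CPM beside Cfd at 41.3 CPM. The lowest log2 fold change of Cfd without any 1 library was 5.11. Expression in liver cells that store fat may account for both genes, a hypothesis with no test here of which cells hold the messages.

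Regrouping single mice at random argued against chance for the number of genes called for diet within each strain and for strain on each diet. This holds only if the mice are independent. No number in the mouse identifiers was shared between groups, so the splits cannot exclude a difference between those numbers. Of 100 splits, the real one included, 1 gave as many genes for diet in 129S1/SvImJ (1514, highest other 157), 1 for diet in C57BL/6J (2159, highest other 978), 1 for strain on chow (3636, highest other 1824) and 1 for strain on high-fat diet (5375, highest other 2263). For the interaction 2 of 100 splits gave as many as the real 43, and the other of these gave 88. These splits moved the diet labels within each strain, which also breaks up the diet effects called in both strains. They therefore cannot exclude chance for the interaction. Its count fell to 5 or fewer under some settings, such as 5 without chow replicate 1 of 129S1/SvImJ.

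The diet effect differed between the strains, by a test of the difference, for 43 genes. Of the genes named, it was higher in 129S1/SvImJ for Nnmt (3.26), Tifa (1.46), Gpat4 (0.843), Crybg3 (0.824), Fh1 (0.682), Rps7 (0.466) and Rpl7a (0.428). It was lower for Tpm2 (-2.76), Mvd (-2.52), Srgap3 (-1.66), Stap1 (-1.48), Cyp51 (-1.38), Fads1 (-1.34) and Tm7sf2 (-0.783). The calls of all but Crybg3, Cyp51 and Fads1 ended without some library. For each of these but Tifa the highest adjusted p was that without chow replicate 2 of 129S1/SvImJ, without which 6 genes were called in all. The difference was also called for 11 gene lists at a preset correlation. Their camera adjusted p was 4.08e-30 for ribosomal proteins, 1.25e-16 for cholesterol synthesis and uptake, 4.62e-08 for male-biased genes, 1.27e-07 for the urea cycle and amino acid breakdown, 1.6e-06 for fatty acid and triglyceride synthesis and 3.29e-05 for fibrosis genes. It was 6.68e-05 for acute-phase genes, 0.000691 for lipid droplets, 0.00074 for Kupffer cell markers, 0.001 for families with near-identical copies and 0.0116 for female-biased genes. With an estimated correlation none of the 11 was called, and with fry only ribosomal proteins were (adjusted p = 0.0238).

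Single libraries stood apart from their group in 48 of 864 group values tested (5.56%), where chance gives about 1 in 20 (43.2). High-fat replicate 3 of 129S1/SvImJ held 12 of them. Its CPM was 7510.0 for Scd1, 3.69 for Cidec (others 1.31 to 1.77), 135 for Adam11, 23.5 for Fabp5 (3.58 to 7.01), 259 for Srebf1 (455 to 597), 171 for Akr1d1 and 32.5 for Ccnd1 (8.2 to 10.9). Its mean log2 CPM was 4.43 for cholesterol genes, 6.95 for fatty acid oxidation genes and 6.57 for antioxidant genes. High-fat replicate 6 of 129S1/SvImJ had 6.707 M counts, 18556 genes detected (others 20020 to 20894) and Hsd17b4 at 576 CPM. High-fat replicate 1 of 129S1/SvImJ had Cidea at 0.0828 and Mcm4 at 4.22 CPM, and replicate 5 had Col3a1 at 46.9 CPM (18.1 to 25.6). On chow, replicate 1 of 129S1/SvImJ had a score of -23.21 on the second principal component and Cfd at 3.21 CPM (0 to 0.225). Replicate 2 had Saa3 at 0.419, Acpp at 0.105 and Col6a3 at 25.1 CPM (9.58 to 12.6), and replicate 3 had Hsd17b4 at 554 CPM and acute-phase genes at 6.9 (mean log2 CPM). Replicate 4 had Ndufb4 at 9.89 CPM, and replicate 5 had Tm7sf2 at 170 and Ndufa10 at 122 CPM.

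In C57BL/6J on high-fat diet, replicate 2 had Adgre1 at 45.3 (16.2 to 23.1) and Il18bp at 21.5 CPM, Kupffer cell markers at 5.33 and interferon genes at 4.61 (mean log2 CPM). Replicate 3 had Rps16 at 23.7 CPM. Replicate 5 had Ces2b at 0.328, Nsdhl at 32.5 (12.9 to 18), Mup11 at 38.8 and Mup20 at 882 CPM, and fatty acid synthesis genes at 8.73 (mean log2 CPM). Replicate 6 had Hsd17b11 at 174, Uqcrc2 at 174 and Igkc at 6.52 CPM (1.52 to 2.64), and replicate 7 had Rn7s2 at 0.227 CPM. On chow, replicate 3 of C57BL/6J had Rpl7a at 151 and Itih3 at 1300 CPM (619 to 808), and acute-phase genes at 7.79 (mean log2 CPM). Replicate 5 had Ctse at 0.466 and replicate 6 had Hsd17b11 at 180 CPM.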

How the results depend on the processing

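The 7SK levels as a term or one at a time, and the fit without both libraries with adipocyte transcripts, were chosen after seeing the data, and the other alternatives before. Over the settings other than leaving out 1 library, named genes kept direction and call in 4105 cases, lost the call in 392, gained it in 39 and turned in 9. Gene lists kept it in 290, lost it in 88, gained it in 5 and turned in 1. The test against a 1.5-fold change called 81 genes for diet in 129S1/SvImJ, 94 for diet in C57BL/6J, 797 and 1133 for strain on chow and high-fat diet, and 1 for the interaction, as a stricter test must call fewer. With upper-quartile factors 747 genes were higher and 805 lower for diet in 129S1/SvImJ (786 and 728 in the main fit), and 1294 and 936 for diet in C57BL/6J (1113 and 1046). For strain on chow they were 1821 and 1831 (1825 and 1811), for strain on high-fat diet 2285 and 3071 (2600 and 2775), and for the interaction 21 and 26 (25 and 18). The direction with more genes thus changed for diet in 129S1/SvImJ, strain on chow and the interaction. With limma-voom it changed for diet in C57BL/6J (1107 higher and 1139 lower) and for strain on high-fat diet (2717 and 2692). With fewer libraries, those of the low 7SK level gave 850, 374, 2123, 2369 and 1 genes in the same order, and those of the high level 172, 746, 1346, 3138 and 0. The interaction had 293 genes by DESeq2, 19 by limma-voom, 17 with the replicate number as a block, 91 with the 7SK level as a term and 2 without both libraries. Of the 24 libraries, 7 were closest to a library of another group with their own replicate number. An estimated correlation left 1 list called for diet in 129S1/SvImJ, 2 for diet in C57BL/6J and 0, 0 and 0 for the others. With fry 1 list was called for diet in 129S1/SvImJ, 8 for diet in C57BL/6J and 1 for the interaction. The number by fry rose to 21 for strain on high-fat diet (15 in the main test), and it rose for strain on chow as well. The high 7SK level gave 7 lists for diet in 129S1/SvImJ and 9 for strain on chow, the low level 9 for strain on chow, and the fit without both libraries 10 for diet in C57BL/6J.

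The Pearson correlation of the strain differences was 0.827 and 0.813 within the low and high 7SK level, and the Spearman correlation 0.57 within the high level. Values of uncalled genes changed sign. For diet in C57BL/6J Axin2 was at -0.463 in the low level and -0.0036 without both libraries. Glul for strain on chow was at 0.0159 without both libraries, and Tcf7l2 for strain on high-fat diet at -0.134 in the low level. In the interaction the low level gave C1qa -0.0468, Tcf7l2 -0.233 and Cyp7a1 -0.279, the high level Lgr5 0.0786, and the fit without both libraries Cyp7a1 -0.288. Kupffer cell markers turned in the interaction in the low level (adjusted p = 0.79). Leaving out 1 library at a time gave 937 to 1671 genes for diet in 129S1/SvImJ, 5 to 170 for the interaction and 5 to 9 lists for strain on chow. Named genes kept direction and call in 6607 such cases, lost the call in 249, gained it in 35 and turned in 16. The fits moved Nnt for diet in 129S1/SvImJ from -0.275 to 0.00363, Axin2 for diet in C57BL/6J from -0.0706 to 0.134, Glul on chow from -0.134 to 0.025, and the interactions of Tcf7l2 from -0.0184 to 0.0995 and of Cyp7a1 from -0.145 to 0.228. Apart from the smaller sets of libraries and the stricter test, the cause was not tested. The depth of 6707013 to 13124881 counts per library limits genes of low abundance, and the mitochondrially encoded genes could not be left out of the library sizes, since they have no counts here.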

Other observations

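The test of strain clustering was written before its result was seen, and the test of clustering within a strain was chosen after it.

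Other gene groups moved with diet in C57BL/6J. Of 18 genes of insulin signalling and the insulin-like growth factor axis 5 fell and none rose (1 higher and 5 lower adjusted over the list alone, median -0.07, camera adjusted p = 0.0268, and 0.572 with an estimated correlation). Of 30 replication-dependent histone genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.0105, and 0.666 with an estimated correlation), and these genes have near-identical copies, so single values are uncertain. Genes of the circadian clock were not called as a list in either strain (adjusted p = 0.444 and 0.894), with 4 rising and 3 falling of 22 in 129S1/SvImJ and 2 and 2 in C57BL/6J. Of 13 genes with higher expression in female liver 8 were lower and 1 higher in 129S1/SvImJ on high-fat diet (8 and 1 adjusted over the list alone, median -0.84), and the list was not called (camera adjusted p = 0.0638).

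Neat1, a long non-coding RNA of nuclear paraspeckles (ENSMUSG00000092274.2), was chosen after its values were seen. It read 5501 ± 2260.0 (SD, n = 6) on chow and 2029 ± 370.0 CPM (SD, n = 7) on high-fat diet in C57BL/6J, with edgeR adjusted p = 0.00169. In 129S1/SvImJ it read 1167 ± 359 (SD, n = 5) and 1228 ± 375 CPM (SD, n = 6), with edgeR adjusted p = 0.92. The interaction was 1.51 (edgeR adjusted p = 0.101), so the diet effect was not shown to differ. Chow replicate 3 of C57BL/6J read 1383 CPM.

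Between the low and the high 7SK level, cut at the widest gap within each strain, 435 genes were called, 349 higher and 86 lower in the high level. The groups held both levels, with 3 low libraries in 129S1/SvImJ on chow, 3 in 129S1/SvImJ on high-fat diet, 3 in C57BL/6J on chow and 2 in C57BL/6J on high-fat diet.

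Genes with a strain difference of at least 2-fold may lie together because sequence differences between the strains act locally. Genes on the fixed list of families with near-identical copies were left out, but other copied genes, such as histone genes and Trim12a, were not. On chow, 27.5% of the 1052 such genes off that list had a non-overlapping neighbour of the same kind, against a mean of 12.0% and a highest value of 17.3% over 1000 shuffles of the gene order. On high-fat diet it was 30.2% of 1304 genes, against 14.9% and 19.6%. Clustering was not specific to strain, since 11% of the genes with a diet change of at least 2-fold within a strain had such a neighbour in either strain, above every shuffle (highest 8.63% and 8.44%). Neighbouring genes that move together for other reasons stay open as an explanation.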
